A study of Mus musculus with 2 samples.

How the data were processed

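The series holds 2 samples of C57BL/6 mice, each deposited as a table of raw read counts per gene symbol. The first covers single neurons of the geniculate ganglion, picked by hand as tdTomato-positive cells of P2rx3-tdTomato mice and sequenced by CEL-Seq, a method that tags RNA at its 3' end. The second covers sorted cells of the tongue epithelium of Pkd2l1-tdTomato mice, as pools of 50 to 100 cells or as single cells, sequenced with a SMART-Seq kit for low input. Per the labels the values are counts of no stated normalization, and the whole numbers and unequal totals of the deposited columns are those of raw counts. Alignment and counting were done with STAR and HTSeq on GRCm38 (mm10), per the submitters' processing notes, which give no versions, no settings and no strand for counting. The ganglion counts are reads and not unique molecules: a cell's counts reach 374856 for 1 gene.

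The taste table had 23521 lines of values and that of the ganglion had 23417. Symbols that a spreadsheet had turned into dates (27 and 25) were left out, because the gene cannot be recovered. They held 0.188% of ganglion reads and at most 1.65% of the reads of a taste library. Also left out were 92 spike-in controls, with at most 3 reads per library, and the summary lines of HTSeq, which gave only the shares of reads outside genes. That left 23393 and 23392 genes, of which 21750 of the taste table (93.0%) matched a symbol of GENCODE release M21, the source of the coordinates. No 2 columns of a table were identical. Groups of pools came from the library numbers in the labels, which list 2 sour and 10 control pools; the table held 2 and 4. The other columns of the taste table were the single sour cells.

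Sour and control pools were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), TMM scaling and its filter for low counts by group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. CPM are reads per 1000000 gene reads of a library. Where a group had no read, the fold is a lower bound against 3 reads over the group's libraries (1.69 CPM for control, 5.07 CPM for sour pools); where it had 1 to 3 reads, no fold is given. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with its preset correlation of 0.01 between genes, and with an estimated correlation; adjusted p-values cover the 12 lists with at least 2 tested genes. Of these, 7 passed with the preset and 1, the type III list, with the estimated correlation. The lists held markers of type I, II and III taste cells, basal cells, keratinocytes, immune, stromal, muscle and salivary gland cells, the otopetrin family, acid-sensing channels, acid-base transport, synaptic release, voltage-gated channels, transmitter synthesis and the cell cycle. The 2 scalings placed the median log2 change of all tested genes at -0.01 (TMM) and 0.02 (DESeq2 size factors).

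For single taste cells, the share of cells with at least 1 read was computed over cells with at least 1000 genes, with exact (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only. A share of 0 is given with the limit that 3 cells of the total allow and the upper end of its exact interval.

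Ganglion reads were split binomially (share 0.5, fixed seed) into a part for clustering and a part for testing. Because reads copied from 1 molecule can fall in both parts, the parts are not independent, and p-values for genes that formed a cluster are too small. Clusters came from log-normalized reads, the 2000 most variable genes, 15 principal components, 15 nearest neighbours and the Leiden method at resolution 1.0 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). They are called by number. For each cluster, reads were summed per experiment over its cells and over all other cells, sums of fewer than 5 cells (2 for cells grouped by a subtype gene) were left out, and edgeR was fitted with experiment as a covariate and the threshold above. In such sums cells with many reads weigh most. The ganglion lists held markers of sensory, visceral and somatosensory neurons, glia, fibroblasts and endothelium, immune and blood cells, the study's subtype genes, and families of receptors, channels, neuropeptides, transcription factors, adhesion genes and early response genes.

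Comparisons, lists, thresholds, most alternatives and the rule for naming genes were set before the data were examined. In the pools the rule named the 10 called genes with the largest and the 10 with the smallest change among those above the median level whose groups did not overlap, up to 4 genes of each list by p, and the otopetrins, 61 genes in all. In the ganglion it named up to 5 called genes per cluster with the largest rise, the 5 subtype genes and up to 3 genes of each list by p. Some genes that the rule named are not reported here, and the closing section's counts over named genes leave them out. Added after their values were seen were Slc4a7, Lyz2, the single-cell shares of Otop2 and Otop3 and the cluster means of P2rx3, Piezo2, Kcns3, Mbp and Apoe. So were Cacna1h in cluster 6, Adtrp in cluster 4 and Fxyd2 in cluster 5. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, plate as a covariate, leaving out each pool or experiment, other minimums, no splitting of reads, another seed and other cluster settings. Chosen after seeing the data were clusters from one part of the genes with tests in the other, equal weight per cell (limma on mean log2(CPM + 50), for genes in at least 5% of cells), cells with at least 2000 genes only, and all comparisons of cells by a single subtype gene. The tests were tried on simulated data of the pool design and of cluster 4. In the pool design 4 of the unchanged genes had an adjusted p under 0.05, and for cluster 4, 0 were called. Figures were drawn with matplotlib 3.10.9.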

Results

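RNA was measured in 2 mouse tissues on the route of sour taste: tongue epithelium, which holds the acid-sensing taste receptor cells, and the geniculate ganglion, whose neurons carry taste signals from the tongue toward the brain. From tongues of Pkd2l1-tdTomato mice, in which sour taste cells carry a red fluorescent protein, the libraries were pools of sorted tdTomato-positive cells (sour pools), pools of tdTomato-negative cells (control pools: other taste cells and supporting cells) and single tdTomato-positive cells. Of the 12 pools that the labels list, the count table held 6, with 188503 and 403166 gene reads in the 2 sour pools and 343757 to 680954 in the 4 control pools. Reads fell on 10325 and 11729 genes in the sour pools and on 10288 to 11184 genes in the control pools. The 56 single cells in the table were all from plate 4 and had 219578 to 914244 gene reads (median 462283) on 447 to 6467 genes. Reads outside annotated genes made up 16.7% and 17.2% of counted reads in the sour pools, 11.6% to 14.5% in the control pools and 18.5% to 45.8% in the single cells. From ganglia of P2rx3-tdTomato mice, 454 hand-picked tdTomato-positive neurons from 8 experiments had 611 to 12716808 reads each (median 805092.5) on 284 to 9745 genes.

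The first comparison asked which genes set sour taste cells apart from the other cells of the tongue epithelium. Otop1, which encodes the proton channel of sour taste cells (chromosome 5, 38275972 to 38304217 in GRCm38), had 647 ± 134 counts per 1000000 reads (CPM; mean ± SD, n = 2) in sour pools and no read in the 4 control pools, and so was at least 384-fold higher (edgeR adjusted p = 5.1e-07). Pkd2l1, the gene used to mark these cells (chromosome 19, 44147637 to 44192442), had 3843 ± 1819 CPM in sour pools and 6.38 ± 6.37 CPM (n = 4) in control pools, 603-fold higher (adjusted p = 1.2e-07). Its partner Pkd1l3 (chromosome 8, 109614517 to 109674386) had 5190.4 ± 2681 against 4.16 ± 3.72 CPM, 1247-fold higher. The other members of the otopetrin family were lower in sour pools, where neither had a read. Otop3 (chromosome 11, 115334731 to 115346927) had 120.2 ± 58.2 CPM in control pools, at least 23.7-fold above sour pools (adjusted p = 2.0e-04). Otop2 (chromosome 11, 115307163 to 115332303) had 64.8 ± 51.2 CPM, at least 12.8-fold above (adjusted p = 0.0113, and 0.0625 without sour pool replicate 1). With 1 member higher and 2 lower, also when adjusted over the list alone, the family as a set did not pass (camera adjusted p = 0.747).

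All 12 tested genes of the 15 on the sour (type III) taste cell list were higher in sour pools, and 12 were when adjusted over the list alone (camera adjusted p = 1.3e-13; adjusted p = 0.0147 with an estimated correlation). Among them Car4, a carbonic anhydrase, had 1265 ± 333 CPM (at least 750.5-fold higher). Ddc, the decarboxylase of serotonin synthesis, had 1360.0 ± 327 CPM (at least 807-fold), and Gad1, which makes GABA, had 479.7 ± 258 CPM (at least 285-fold). The secretory granule gene Chga had 1346 ± 542 CPM (at least 799-fold). None of these 4 genes had a read in a control pool. The cell adhesion gene Ncam1 had 944 ± 68.3 against 1.38 ± 1.60 CPM. Scg2, Tph1 and Kcnj2 had too few reads to test. Pkd2l1, whose reporter was used to sort the cells, is also on this list, so the sort favoured its rise beforehand. All 17 tested genes of the 26 on the synaptic vesicle release list were higher, and 17 when adjusted over the list alone (camera adjusted p = 1.4e-12; adjusted p = 0.0577 with an estimated correlation). Snap25, a membrane fusion protein gene that is on both lists, had 2067 ± 245 against 0.656 ± 1.31 CPM, with 1 read in all control pools (adjusted p = 4.7e-08). Cplx2 had 819.8 ± 139 against 2.77 ± 2.15 CPM (296-fold higher), Rab3a had 272 ± 72.7 against 3.38 ± 2.52 CPM (80.6-fold higher), and Pclo had 142 ± 1.31 against 1.04 ± 1.29 CPM.

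The genes with the largest fitted rise outside these lists were Nov, Tspan1, Tmem45b, Vil1, Cib3 and Snhg11. Nov, which encodes a secreted matrix protein, had 3749.7 ± 887 CPM (at least 2225-fold higher), Tspan1 had 2461 ± 467 CPM (at least 1459.8-fold) and Tmem45b had 1632 ± 355 CPM (at least 969-fold). Vil1, which bundles actin in microvilli, had 1609 ± 350.0 CPM (at least 955-fold), and Cib3, a calcium-binding protein gene, had 1001 ± 339 CPM (at least 594-fold). These 5 had no read in control pools. Snhg11 had 12760.4 ± 1121 against 4.66 ± 7.51 CPM, 2736-fold higher. Krt7, a keratin of simple epithelia and the 1 tested gene of the 8 on the salivary gland list, had 15389.9 ± 202 against 247 ± 121 CPM, 62.2-fold higher.

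Keratin genes of the stratified tongue epithelium were far lower in sour pools. Of 8 tested lingual basal and progenitor genes, 7 were lower, and 7 when adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.0943 with an estimated correlation). Krt14 had 142 ± 24.8 CPM in sour and 19328 ± 2721 CPM in control pools, 137-fold lower. Krt15 had 42.9 ± 30.6 against 10643 ± 2139 CPM, 248-fold lower, and Col17a1, a collagen of the epithelial basement attachment, had no sour read against 1435 ± 623 CPM, at least 283-fold lower. Of 11 tested keratinocyte genes 9 were lower, and 10 when adjusted over the list alone (camera adjusted p = 2.4e-05; adjusted p = 0.12 with an estimated correlation). Krt4 (chromosome 15, 101918535 to 101924735) had 963 ± 281 against 28474 ± 10630.0 CPM, 29.6-fold lower, and Krt13 had 599.7 ± 209.7 against 13654 ± 2457 CPM, 22.8-fold lower. Of 15 cell cycle genes 13 were lower, and 14 when adjusted over the list alone (camera adjusted p = 1.7e-09; adjusted p = 0.0943 with an estimated correlation). Mki67, a marker of dividing cells, had no sour read against 211 ± 67.4 CPM, at least 41.6-fold lower, and the mitotic gene Cdc20 had 6.55 ± 5.75 against 644 ± 152 CPM. Dcn, a connective tissue proteoglycan gene and the 1 tested gene of the 10 on the stromal and endothelial list, had 52.4 ± 46 against 2589.8 ± 234 CPM, 49.5-fold lower. Other genes without a sour read were the gap junction gene Gja1 (1836 ± 955 CPM in control pools, at least 362-fold lower) and Wnt10a (420.3 ± 67.5 CPM, at least 82.9-fold).

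Ion channel genes were among those higher in sour pools, including Pkd2l1, whose reporter was used to sort the cells. The sort favoured its rise beforehand, and the list below that holds it was not tested without it. On the list of acid-sensing, PKD, HCN and acid-sensitive potassium channels, 4 of 5 tested genes were higher, and 4 when adjusted over the list alone (camera adjusted p = 0.0080; adjusted p = 0.211 with an estimated correlation). Beside Pkd2l1 and Pkd1l3 these were the potassium channel gene Kcnk1, with 569 ± 61.8 against 33.7 ± 14.7 CPM (16.9-fold higher, adjusted p = 3.5e-06), and Pkd1, with 104 ± 64.0 against 32.9 ± 7.47 CPM (adjusted p = 0.0253). Pkd1 did not pass without sour pool replicate 1 (adjusted p = 0.581), control pool replicate 2 (0.0573) or control pool replicate 6 (0.0531). Of 4 tested voltage-gated sodium and calcium channel genes 3 were higher, and 3 when adjusted over the list alone (camera adjusted p = 0.0089; adjusted p = 0.113 with an estimated correlation). Scn3a had 149 ± 23.7 CPM against no control read, at least 88.6-fold higher. Cacna1a had 80.5 ± 8.87 against 4.46 ± 2.92 CPM (adjusted p = 0.0514 without sour pool replicate 1) and Cacna1c had 35.6 ± 12.8 against 1.39 ± 1.61 CPM (adjusted p = 0.0549 without sour pool replicate 2). Carbonic anhydrase and acid-base transport genes went both ways, with 3 higher and 2 lower of 7, also when adjusted over the list alone (camera adjusted p = 0.482). Car4, Car11 (75.5 ± 50.7 CPM against no control read) and the bicarbonate transporter gene Slc4a7 (107 ± 23.9 against 8.22 ± 12.2 CPM) were higher. Car12 (19.8 ± 28.1 against 493 ± 258 CPM) and Car13 (11.7 ± 5.99 against 169 ± 29 CPM) were lower. Of 4 tested monoamine, GABA and acetylcholine genes, Ddc and Gad1 were higher, 2 when adjusted over the list alone (camera adjusted p = 0.106), while the serotonin transporter gene Slc6a4 had 9.92 ± 14 against 49.9 ± 32.8 CPM (adjusted p = 0.124).

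Markers of other cell types had few tested genes. Enough reads to test were found for 1 of 16 type II and 2 of 6 type I taste cell genes. For basal and keratinocyte genes these were 8 of 11 and 11 of 13. The comparison is thus mainly one with cells that carry keratin transcripts. It does not show that a gene sets sour cells apart from other taste cells. Itpr3, a calcium release channel and the 1 tested gene of the sweet, umami and bitter (type II) list, had 46.7 ± 24.0 CPM in sour and 110.1 ± 55.7 CPM in control pools (adjusted p = 0.115), and was lower only when adjusted over the list alone, which then is its own p. On the glia-like (type I) list Hes1 was lower, 24.3 ± 4.29 against 263 ± 244 CPM (adjusted p = 0.0040), and Entpd2 had 37.5 ± 38.1 against 45.1 ± 18.5 CPM (adjusted p = 0.882); that made 1 of 2 lower, also when adjusted over the list alone (camera adjusted p = 0.308). Of 3 tested immune genes 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.747). This was H2-Ab1, with 12.4 ± 17.5 against 198 ± 273 CPM (adjusted p = 0.0331), which did not pass with DESeq2 (0.0686), without control pool replicate 2 (0.106) or without sour pool replicate 2 (0.121). The myeloid genes Lyz2, with 1911 ± 2703 against 7.86 ± 12.5 CPM, and Csf1r, with 94.3 ± 133 against 20.3 ± 40.7 CPM, had reads in 1 of the 2 sour pools, replicate 1. No gene of the 8 on the muscle list had enough reads to test.

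In total edgeR tested 7739 genes, of which 1158 were higher and 1113 lower in sour pools (adjusted p under 0.05 and at least 2-fold), and 3007 had an unadjusted p under 0.05. In 48.6% of all tested genes the 2 groups of pools did not overlap, which chance gives for 13.3% of genes. Fewer genes were called without either of the sour pools, which leaves 1 sour library each time. The part that the myeloid reads of sour pool replicate 1 had in the calls was not tested. In simulated counts of the same design, with 200 genes changed, 39.4% of 4-fold and 4.30% of 2-fold changes had an adjusted p under 0.05 in the right direction. With so few changed genes the adjusted threshold is stricter than in the real comparison, so these shares do not measure its sensitivity. Still, a gene without a call is not shown to be alike in both groups. The labels do not say whether pools or ganglion experiments came from separate animals, so p-values here measure only the spread between these libraries.

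**Figure D1:**
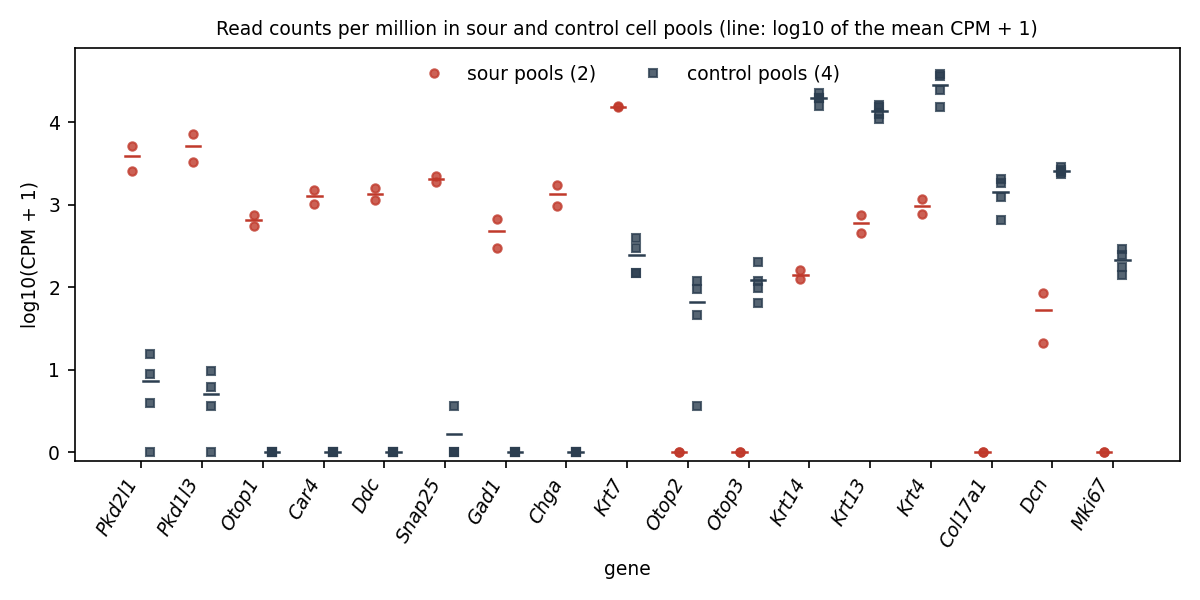
CPM of 17 genes in each sour pool (circles, 2) and control pool (squares, 4), on the scale log10(CPM + 1), with a line at the log10 of each group's mean plus 1. Otop1, Car4, Ddc, Gad1 and Chga lie at 0 in the 4 control pools, and Otop2, Otop3, Col17a1 and Mki67 lie at 0 in both sour pools.

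The single sour taste cells showed how the genes of the sour pools were spread over cells. Of 52 cells with reads on at least 1000 genes (median 475248.5 gene reads), all had Snap25 and Ncam1 (100%, exact 95% binomial interval from 93.2%). Pkd2l1 was seen in 98.1% (89.7% to 100.0%), Ddc in 96.2%, Pkd1l3 in 92.3% (81.5% to 97.9%) and Otop1 in 86.5% (74.2% to 94.4%). Otop1 and Pkd2l1 were seen together in 45 cells, Pkd2l1 without Otop1 in 6, Otop1 without Pkd2l1 in 0 and neither in 1. Otop3 and Otop2, without a read in sour pools, were seen in 4 and 3 of the 52 cells (7.69% and 5.77%). Car4 was seen in 84.6%, Gad1 in 76.9%, Chga in 73.1%, Chgb in 69.2% and Scg3 in 46.2%. Kcnj2 was seen in 15.4%, and Tph1, the first enzyme of serotonin synthesis, and Scg2 in 3.85% each. A cell had a median of 11 of the 15 type III genes, with a range of 5 to 14.

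Genes called higher in sour pools were seen in a median of 53.8% of the single cells and took a median of 31.2% of a cell's gene reads. Genes called lower were seen in a median of 19.2% of cells and took 5.73% of gene reads, and genes with no call were seen in a median of 38.5%. Some keratin genes that were lower in sour pools were nevertheless seen in most single sour cells. Krt4 had a read in 94.2% of cells (median 685 CPM) and Krt13 in 92.3% (median 227 CPM). The basal keratins Krt14 and Krt15 had a read in 53.8% and 51.9%, Krt5 in 46.2%, and Dcn in 42.3%. Krt7 was seen in 98.1% of cells. Of the other taste cell lists, the most widely seen genes were Hes1 (57.7%), Itpr3 (23.1%) and Entpd2 (11.5%), and of the immune list H2-Ab1 (13.5%) and Cd74 (9.62%). The muscle gene Acta1 was seen in 9.62%. Aqp5, Actn3 and Ckm were seen in 0 of 52 cells, which allows a share of cells with a read of up to 5.77% by 3 cells of the total and 6.85% by the exact 95% interval. Wells without a cell are not in the table, so no background share could be measured.

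**Figure D2:**
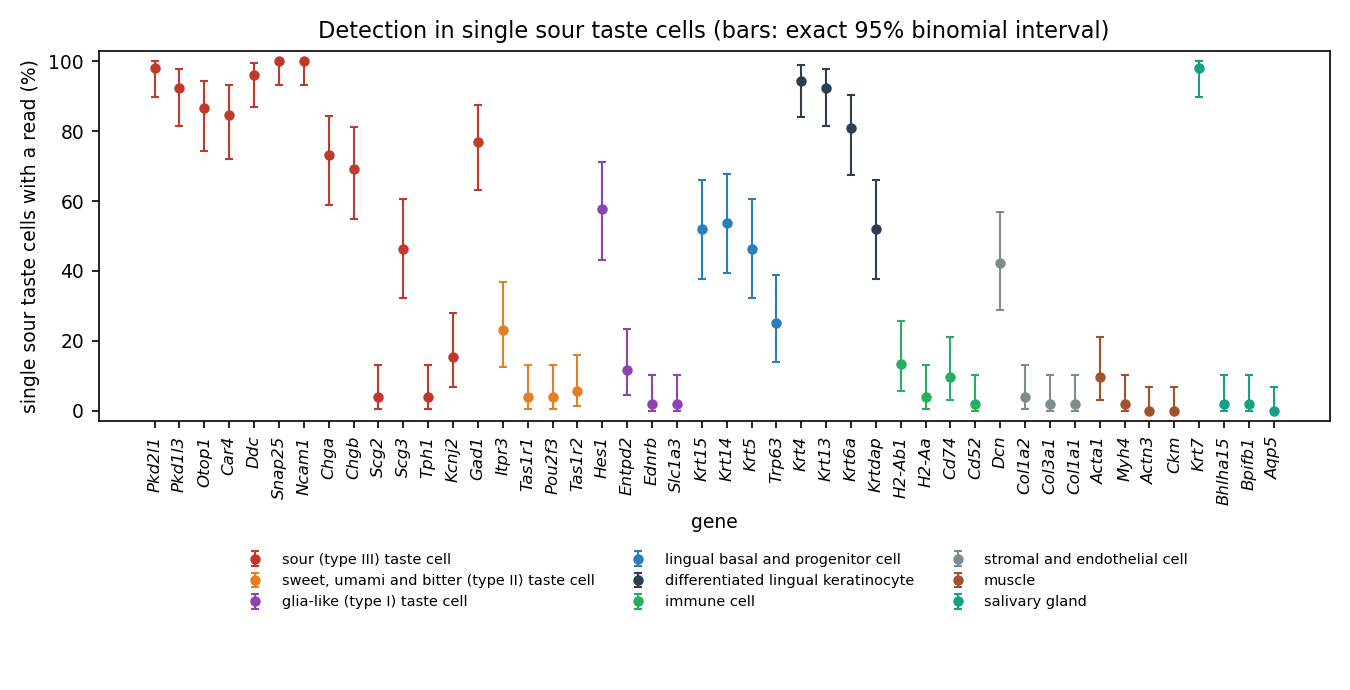
Share of 52 single sour taste cells with at least 1 read of each gene, in percent, with exact 95% binomial intervals as bars and colours for the gene lists. Snap25 and Ncam1 lie at 100%, Otop1 at 86.5% and the keratinocyte gene Krt4 at 94.2%.

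In the geniculate ganglion the question was which kinds of neuron the picked cells hold and what sets them apart. The 454 neurons fell into 7 clusters of 80, 74, 73, 73, 67, 47 and 40 cells, from 17.6% (exact 95% interval 14.2% to 21.4%) to 8.81% (6.37% to 11.8%) of all cells. The purinergic receptor gene P2rx3 had means of 974 to 2120 CPM in clusters 1 to 5 and 501 and 373 CPM in clusters 6 and 7. Piezo2, a mechanosensory channel gene, had its highest means in clusters 6 and 7, 593 and 532 CPM, as had the potassium channel gene Kcns3, with 401 and 369 CPM. Cluster 2 stood out by glial transcripts, with means of 1858 CPM for the myelin gene Mbp and 2354 CPM for Apoe. Cluster 3 held cells with few reads, a median of 50221 per cell on 1264 genes, 6.24% of the median of all cells. Clusters were uneven over experiments, cluster 2 taking 4.48% to 56.9% of an experiment's cells, and other clustering settings gave 5 to 8 clusters. Membership changed with them: the adjusted Rand index with the 7 clusters (1 for identical groupings, about 0 for unrelated ones) was 0.384 with genes centred within experiment, 0.420 with 1000 variable genes, 0.490 with cells of at least 1000 genes and at most 0.899, at resolution 1.4.

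**Figure D3:**
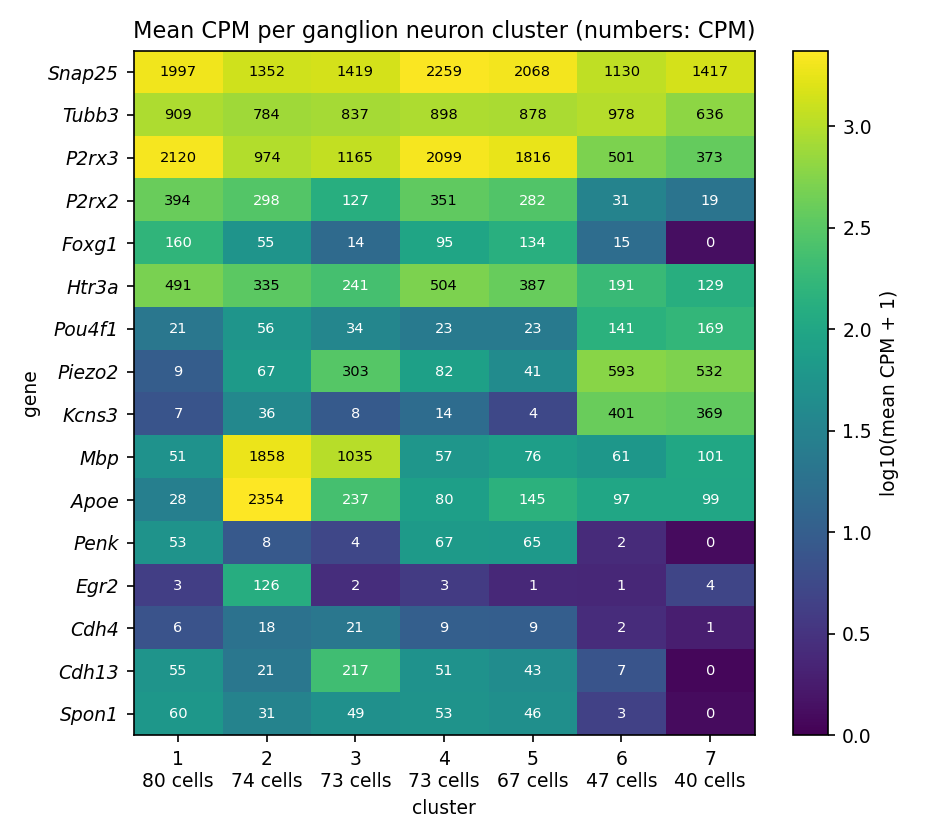
Mean CPM over the cells of each ganglion cluster (columns) for 16 genes (rows), with the mean printed in each field and log10(mean CPM + 1) as colour. Piezo2 and Kcns3 are highest in clusters 6 and 7, and Mbp and Apoe are highest in cluster 2.

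Each cluster was then tested against the other cells of the same experiments. Cluster 7 (40 cells; sums from 3 experiments) had less P2rx3, with 167 ± 123 CPM (SD, n = 3) against 999 ± 206 CPM in the other cells, a log2 change of -2.64 (SE 0.39, edgeR adjusted p = 0.0145, lower in 3 of 3 experiments). It also had less P2rx2 (13.5 ± 6.76 against 198 ± 88.9 CPM), the growth gene Gap43 (88.1 ± 79.9 against 1424 ± 432 CPM), the neuropeptide gene Nts and the placode gene Eya1. It had more Fxyd2, a sodium pump subunit gene, with 2315.5 ± 867 against 452 ± 139 CPM (log2 change 2.58, SE 0.32, adjusted p = 0.0058, higher in 3 of 3), Pcp4 (4222 ± 331 against 1380.4 ± 455 CPM), Cd24a (1196 ± 457 against 295 ± 131 CPM) and Ak5. In all 12 genes were higher and 27 lower. Pcp4 and Cd24a passed in all 12 alternatives, Fxyd2, P2rx2 and P2rx3 in 11, Gap43, Nts and Eya1 in 10 and Ak5 in 8. The count of 39 was 51, 121 and 114 without experiments JC07, JC08 and JC09, and was 8 with clusters from one part of the genes and tests in the other.

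Cluster 6 (47 cells; 6 experiments) had more Piezo2 (chromosome 18, 63010213 to 63387183), with 629.8 ± 217 against 105 ± 114 CPM (log2 change 3.67, SE 0.77, adjusted p = 0.0448, higher in 6 of 6 experiments), and more Pde1c (351 ± 98.8 against 57.8 ± 58.6 CPM) and Sorl1. It had less of the GABA receptor gene Gabrb2 (139 ± 81.4 against 1126 ± 144 CPM, adjusted p = 0.0077) and of Chrna3. The neuropeptide genes Tac1 (19.5 ± 24.6 against 589 ± 405 CPM), Calca and Adcyap1 were lower, as was Spon1 (1.19 ± 1.99 against 40.7 ± 24.3 CPM). In all 53 genes were higher and 111 lower. The count of 164 was 22, 11, 104, 16 and 21 without experiments JC04, JC05, JC08, JC09 and JC11, and 7 with another random split of the reads. Gabrb2 passed in 13 of 15 alternatives, Chrna3 and Calca in 11, Adcyap1 in 9, Pde1c and Tac1 in 8, Spon1 in 7 and Sorl1 in 6. Piezo2 passed in 6 of 15, where its log2 change was 2.63 to 4.26 and its adjusted p 5.4e-10 to 0.212.

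In cluster 1 (80 cells; 7 experiments) Piezo2 was lower, 8.57 ± 10.1 against 305 ± 147 CPM (log2 change -6.28, SE 0.92, adjusted p = 0.0118, lower in 7 of 7 experiments), as was Kcns3 (5.47 ± 7.33 against 171 ± 117 CPM). The guidance receptor gene Nrp1 and the serotonin receptor gene Htr1d were lower as well. Gabrb2 was higher, 1747 ± 281 against 766 ± 363 CPM (log2 change 1.34, SE 0.19, adjusted p = 0.0110, higher in 7 of 7), and so were the thrombin receptor gene F2r (251 ± 75.6 against 104 ± 66.6 CPM), Basp1, Efr3a and Mdga2. In all 6 genes were higher and 35 lower. Gabrb2 and Kcns3 passed in 13 of 16 alternatives, Nrp1 in 12, Piezo2 in 11, Basp1 in 8, F2r in 7, Efr3a in 6, Htr1d in 5 and Mdga2 in 4. The count of 41 was 13, 19, 15, 16, 70 and 18 without experiments JC04, JC07, JC08, JC09, JC10 and JC11, and 2 with clusters and tests from all reads, where clusters 1 and 4 were matched to the same new cluster.

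Cluster 2 had no gene past the threshold with edgeR and its filter. At an unadjusted p under 0.05, which chance gives for a share of about 0.05 of tested genes, it had 714 genes. Without a filter edgeR called 193, DESeq2 called 479 and limma on equally weighted cells called 4. The glial gene Mbp did not pass, with 399 ± 295 against 46 ± 27 CPM (log2 change 2.91, SE 0.46, adjusted p = 0.0871, higher in 6 of 6 experiments). It passed without a filter (adjusted p = 1.6e-11), with DESeq2 (2.8e-10) and with cells weighted equally (0.0381). With clusters and tests from all reads its log2 change was -0.39, in a matched cluster that shared only part of the cells (Jaccard index 0.424). Of 10 tested glial genes 6 were higher when adjusted over the list alone, of 4 fibroblast and endothelial genes 3, among them Col1a2 (127 ± 112 against 6.36 ± 4.92 CPM), and of 15 immediate early genes 4, among them Egr1 (169 ± 122 against 26.3 ± 7.96 CPM). Without experiment JC10 the cluster had 16 genes past the threshold, with Mbp, Col1a2 and Egr1 among them (adjusted p = 0.0105, 0.0105 and 0.0333), and without JC04 it had 2.

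Cluster 3, the cells with few reads, had 7 genes higher and 3069 lower. Among the higher were the ribosomal RNA gene Rn45s, with 35585 ± 16957 against 13617 ± 12603 CPM (log2 change 2.24, SE 0.22, adjusted p = 4.5e-20, higher in 6 of 6 experiments), Tmsb4x (20014 ± 9849 against 12835 ± 6243 CPM) and Gas5. Gas5 was lower, not higher, when cells were weighted equally (log2 change -0.63, under 2-fold; adjusted p = 0.0381, and 0.0032 to 0.140 over its alternatives). Rn45s, Kcnip4 and Scn11a passed in 13 of 14 alternatives, Tmsb4x in 10 and Gas5 in 7. The lower genes included the channel genes Kcnip4 and Scn11a, which had no read in the cluster. The lower genes went with the low depth of these 73 cells, whose median of 50221 reads compares with 805092.5 over all cells. Cluster 4 had 1 gene past the threshold, Adtrp, lower at 1.23 ± 2.31 against 98.2 ± 71.4 CPM (adjusted p = 0.0346), and cluster 5 had 1, Fxyd2, lower at 30.9 ± 35.2 against 412 ± 334 CPM (adjusted p = 0.0371). Both were named after their values were seen. Each count was 0 in some runs, for cluster 4 without JC07, JC09, JC11 or JC12 and for cluster 5 without JC08, JC09 or JC11, and both were 3 without JC10. In other runs the counts were larger. For clusters 4 and 5 they were 702 and 1934 with DESeq2, and 4 and 316 with another random split of the reads. In simulated counts for cluster 4, 0% of 4-fold changes were called, so few calls there do not show that the clusters were alike.

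Of the lists set for the ganglion, the clusters with the most called genes are given here, and the shallow cluster 3 only where it is named. Visceral ganglion genes had 2 of 6 tested lower in cluster 6 (4 adjusted over the list alone) and 3 of 6 in cluster 7 (3 adjusted over the list alone, with 1 higher). Of 4 somatosensory ganglion genes 2 were lower in cluster 6, Calca and Tac1 (2 adjusted over the list alone). Neuropeptide and glutamate transport genes had 4 of 9 lower in cluster 6 (5 adjusted over the list alone, with 2 higher). GABA, glutamate and acetylcholine receptor genes had 3 of 18 lower in cluster 6 (5 adjusted over the list alone) and 1 of 20 higher in cluster 1 (2 adjusted over the list alone, with 1 lower). Purinergic and serotonin receptor genes had 2 of 11 lower in cluster 7 (3 adjusted over the list alone). Mechano-, thermo- and acid-sensing channel genes had Piezo2 alone, higher in cluster 6 (2 adjusted over the list alone, with 1 lower) and lower in cluster 1 (1 adjusted over the list alone). Voltage-gated channel genes had 1 of 32 higher in cluster 6, Cacna1h (5 adjusted over the list alone, with 2 lower), and Kcns3 lower in cluster 1 (1 adjusted over the list alone). Transcription factor genes had 2 of 32 lower in cluster 6 (11 adjusted over the list alone, with 1 higher) and 3 of 31 in cluster 7 (6 adjusted over the list alone, with 1 higher). Cadherin, semaphorin, plexin and ephrin genes had 2 of 31 lower in cluster 6 (5 adjusted over the list alone, with 2 higher), Nrp1 lower in cluster 1 (3 adjusted over the list alone) and Epha5 lower in cluster 7 (1 adjusted over the list alone, with 1 higher). Sensory neuron genes had 1 of 12 lower in cluster 7, Gap43 (1 adjusted over the list alone). Neurotrophic factor receptor genes had 4 of 11 lower in cluster 3 (5 adjusted over the list alone). In cluster 3, however, 3076 genes passed in all and lower genes went with low depth, so nothing particular to this list follows. In cluster 6 the list had 2 lower and 1 higher when adjusted over the list alone. No gene of the immune and blood cell list had enough reads to test. Of the study's subtype genes Penk, Egr2, Cdh4, Cdh13 and Spon1, edgeR called Spon1 lower in cluster 6 and Penk lower in cluster 3. These genes were chosen on these cells and so are not independent evidence of a direction. Penk in cluster 3 passed in 3 of 14 alternatives. Adjusted over the list alone, 5 of 5 subtype genes were lower in cluster 6 and 4 of 5 in cluster 7.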

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

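The counts of splits for the pools and for cells with Penk, Cdh13 or Spon1, the keratin test of an equal share, the Pearson correlation and the glial ratio for Egr2 were chosen only after the result was seen. Among 61 groups of 4 to 10 values examined for a library far from the others, 8 had one, where chance gives about 1 in 20. Control pool replicate 1 had 680954 gene reads against 343757 to 381042 in the other control pools, and 44.1 CPM of Pkd1 against 28.9 to 29.4. In control pool replicate 4, 1.79% of counted reads were ambiguous between genes, against 1.38% to 1.42%. Hes1 had 628 CPM in control pool replicate 6 against 118 to 158. Control pool replicate 2 held 4 of the 8, the immune genes H2-Ab1 (606 CPM against 47 to 90.9), Cd74 (706 CPM against 0 to 2.67) and Csf1r (81.4 CPM against 0) and the synaptic gene Snap25 (2.62 CPM, 1 read, against 0). For Csf1r and Snap25 the other control pools were at 0, so a single read would have been enough to stand out. Snap25 had 1 read there, while Csf1r had 31. The cause was not tested. A signal outside the gene comparisons was the tdTomato transcript, the marker by which the sour cells were sorted. It had reads in 16 of the 56 single cells (28.6%, up to 22 reads in a cell), 1 read in the sour pools and 0 in the control pools.

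Whether chance can be excluded for the counts of genes was examined by assigning the libraries to groups in other ways. The 6 pools can be split into 2 and 4 in 15 ways, too few for a share under 0.05; the real split gave 2271 genes and the highest of the others 0. For ganglion clusters the sums of an experiment were swapped between cluster and other cells, in up to 22 ways with the real one, drawn with a fixed seed where more exist. As many genes as the real way came in 1 of 22 ways for cluster 1 (real 41, highest other 3), cluster 3 (real 3076, highest other 5) and cluster 6 (real 164, highest other 0), in 2 of 22 for cluster 4 (real 1, highest other 1) and in 22 of 22 for cluster 2 (real 0, highest other 2). For cluster 5 there were 16 ways and for cluster 7 there were 4, too few for a share under 0.05. Their real counts were 1 and 39, the highest others 1 and 0, and 2 and 1 ways gave as many. For the cells grouped by a subtype gene 1 of 22 ways each gave as many (Penk real 426, highest other 0; Cdh13 real 9, highest other 0; Spon1 real 219, highest other 1). These cells were grouped by reads that were then tested, and the clusters by reads that are not independent of the tested ones. Either favours the real grouping beforehand, and a swap breaks it up, so nothing follows about chance for any cluster or subtype gene.

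Keratin reads in single sour taste cells may in part be RNA of lingual keratinocytes in the wells, a hypothesis from these same data. Over 52 cells the sum of the keratinocyte list, of whose 13 genes 11 had reads in sour pools and Krt4 and Krt13 the most, went with the sum of 1073 other genes lower in sour pools at Spearman rho = 0.802 (permutation p = 1.0e-05, the smallest that the permutations can give; adjusted p = 1.5e-05 over the 3 correlations computed; Pearson r = 0.839, adjusted p = 1.5e-05, and 0.787 without the 2 farthest cells), but not with the 5453 genes of no call (rho = -0.00188, p = 0.990, adjusted p = 0.990). For an equal small share of control pool reads in each library, the spread over cells was examined. The 90th percentile of the list was 20.2 times the 10th (11951 and 593 CPM, median 1413 CPM). Control pools had 51363 and sour pools 2033 CPM of the list. The bound for this ratio was set after the result was seen. The spread that few molecules per well give was not measured, so the ratio cannot decide about an equal share. The cells were sorted for tdTomato, a gate that should remove keratinocytes but not their free RNA, and the sour cells' own expression stays open. The labels give no group for a biological explanation, and none was tested.

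Egr2 was seen at 100 CPM or more in 15 cells, of which 13 were in cluster 2, and RNA of Schwann or satellite cells may be a source (Egr2 is both on the glial list and among the study's subtype genes). The sum of 12 other glial genes, among them Fabp7 and Apoe (means 2574 and 2354 CPM in cluster 2), was compared. Its median was 6167 CPM in those 15 cells and 2030.1 CPM in 356 other cells, a ratio of 3.04 (permutation p = 2.0e-05). That is close to the bound of 3, which was set after the data were seen. As 13 of the 15 lay in cluster 2, which stood out by glial transcripts, the test was not independent of that observation. Whether glial RNA alone would do was left open: of 27 cells with as much glial RNA as the median Egr2 cell, 8 had Egr2 (29.6%, 13.8% to 50.2%). The cut was the median of the 15 Egr2 cells themselves, which fixes the 8 beforehand. Only the 27 was observed, so the interval is no sampling error and the share cannot decide the question. The cells were picked by hand for tdTomato, which attached glia would pass. The labels give no group for a biological explanation, and none was tested.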

How the results depend on the processing

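Some runs were chosen only after the data were seen. They were clusters from one part of the genes with tests in the other, and equal weight per cell. Also among them were tests of the same clusters in cells with at least 2000 genes only, and another seed for the number of clusters. All tests of cells by a subtype gene were chosen then too. Unless a sentence says otherwise, the cause of a change was not tested. The alternatives set for normalized values, another pseudocount and no filter on low values, were not run, because the values are counts.

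In the pools 675 of 702 pairs of a named gene and an alternative kept direction and side of the threshold, 8 came past it, 9 fell short and 10 reversed. The count of 2271 genes was 2287 with DESeq2 size factors, 2150.0 with DESeq2, 2993 without a filter, 2427 and 2399 with plate as a covariate (all pools; plates 1 and 3), 2288 on adjusted p alone and 1399 to 2505 leaving out each pool, the lowest without sour pool replicate 1, where the lone sour pool is assumed to vary like the control pools. The 7 gene lists fell to 1 with an estimated correlation. Reversed, none past the threshold, were Maoa (-0.25; 0.14 with plate, 0.12 with plates 1 and 3, -1.66 to 0.53 leaving out each pool), Csf1r (2.30; -6.00 to 3.20), Cacnb3 (0.16; -1.41 to 0.96) and Entpd2 (-0.18; -2.12 to 0.46).

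In single taste cells the number of type III genes seen in at least 50% of cells was 11, 12 in cells with at least 2000 genes and 11 at 5 or more reads; 82 of 92 pairs for named genes moved by less than their interval. Depth limits this comparison, since a gene of few molecules can be missed in a cell that has it.

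The largest ganglion cluster had 17.6% of cells, 26.7% at resolution 0.6, and 22.2% with 1000 variable genes or no splitting of reads. For clusters 1 to 7 the counts were 41, 0, 3076, 1, 1, 164 and 39. Clusters of a new run were matched by shared cells, with Jaccard indices down to 0.298. With all reads for clusters and tests, clusters 1 and 4 were matched to the same new cluster, which had 2, and clusters 2, 5 and 6 had 10, 0 and 254. With another seed of the split, clusters 1, 2, 4, 5, 6 and 7 had 26, 2, 4, 316, 7 and 22. With at least 10 cells per sum, which leaves fewer sums, clusters 1, 3, 4, 5 and 6 had 4, 1417, 0, 0 and 40, and cluster 2 had too few experiments to give a value. DESeq2 gave clusters 1, 2, 4, 5, 6 and 7 765, 479, 702, 1934, 1531 and 1137. No filter gave clusters 1, 2, 5 and 6 93, 193, 2 and 352, and DESeq2 size factors gave cluster 5 2. Genes in 2 parts gave clusters 1, 2, 4, 5, 6 and 7 11, 9, 4, 0, 5 and 8; in 1 of the parts clusters 1 and 4 again had the same match. Equal weight gave clusters 1, 2, 3, 4, 5 and 7 127, 4, 881, 18, 0 and 84. Cells with at least 2000 genes gave clusters 2 and 5 2 each, and no value for cluster 3. Leaving out each experiment gave 13 to 70 for cluster 1 (13, 19, 15, 16, 70 and 18 without JC04, JC07, JC08, JC09, JC10 and JC11), 0 to 16 for 2 (2 without JC04, 16 without JC10), 0 to 3 for 4 (0 without JC07, JC09, JC11 or JC12, 3 without JC10) and for 5 (0 without JC08, JC09 or JC11, 3 without JC10), 11 to 191 for 6 (22, 11, 104, 16 and 21 without JC04, JC05, JC08, JC09 and JC11) and 51 to 121 for 7 (121 and 114 without JC08 and JC09). Where a count was 0 with edgeR, the unadjusted p was under 0.05 for 477 (cluster 4) and 484 (cluster 5) genes with 10 cells per sum, 1238 and 989 in cluster 5 with all reads and with genes in 2 parts, and 1772 with limma at equal weight. Leaving out experiments, these were 581 to 623 in cluster 2, 633 to 893 in cluster 4 and 945 to 1049 in cluster 5. Chance gives an unadjusted p under 0.05 for a share of about 0.05 of tested genes. Such counts alone therefore do not show a difference.

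For named ganglion genes 891 of 1169 pairs were unchanged, 35 came past the threshold, 196 fell short and 47 reversed. Counted with Htr3a, Tac1 and P2rx3 in cells grouped by a subtype gene, 46 were past the threshold. These 3 were chosen after the data were seen and are not in the 1169 pairs. Of the 46, 4 stayed there under each alternative (Cd24a and Pcp4 in cluster 7, Htr3a in cells with Penk, Tac1 in cells with Spon1). In at least 80% of the alternatives 20 stayed there. None of the reversed values was past the threshold; Gas5 in cluster 3 with equal weight (-0.63) had an adjusted p of 0.0381 but was under 2-fold. With all reads the reversed were in cluster 2 Mbp (-0.39), Penk (1.64) and Spon1 (0.22), in cluster 4 Penk (0.36) and in cluster 5 Cdh13 (0.77) and Spon1 (1.46). With another seed they were Cdh4 in cluster 1 (1.07), Cdh13 in cluster 2 (0.45) and Penk in cluster 4 (0.45), and with 10 cells per sum Spon1 in cluster 1 (-0.29), Penk in cluster 4 (0.11) and Cdh13 in cluster 5 (0.48). Spon1 in cluster 5 had 0.017 with DESeq2 and 0.014 with its size factors. Genes in 2 parts gave Penk in clusters 2 and 4 1.33 and 1.05, Cdh13 in clusters 4 and 5 -0.34 and 1.93 and Spon1 in cluster 5 0.83. Equal weight gave Cdh4 in clusters 1 and 3 0.039 and 0.036, Spon1 in clusters 2 and 5 0.13 and 0.035, and Penk in clusters 4 and 5 0.16 and 0.11. Leaving out each experiment gave, in cluster 1, Cdh4 -2.47 to 0.21, Spon1 -0.40 to 0.56 and Penk -0.38 to 2.14; in cluster 2, Penk -2.14 to 0.16, Spon1 -0.96 to 0.62 and Cdh13 -0.97 to 0.26; in cluster 4, Penk -1.08 to 0.82 and Cdh13 -0.15 to 0.99; in cluster 5, Cdh13 -1.28 to 0.12 and Spon1 -0.91 to 0.58.

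Cells with Penk, Cdh13 and Spon1 had 426, 9 and 219 genes past the threshold, of which 411, 7 and 201 were lower. These counts were 33, 4 and 11 for cells at 50 CPM or more, and 14 and 1 (Penk, Cdh13) at 200 CPM or more. Against cells with another subtype gene they were 10, 0 and 4. There Cdh13 had 388 of 9106 tested genes at an unadjusted p under 0.05, a share below the 0.05 that chance gives. The counts were 3322, 2178 and 2418 with DESeq2, 11, 5 and 5 without a filter, and 3, 1 and 7 with equal weight. Leaving out each experiment gave 4 to 17, 1 to 9 and 12 to 418.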

Other observations

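All tests of cells grouped by a subtype gene, the level of 100 CPM and the 2 pairs of genes below were chosen only after the data were seen.

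Geniculate neurons that expressed Penk, an opioid peptide gene (chromosome 4, 4133531 to 4138819), also had the serotonin receptor gene Htr3a (chromosome 9, 48899213 to 48911099). Of the 371 neurons with at least 2000 genes, 22 had Penk at 100 CPM or more (5.93%, exact 95% interval 3.75% to 8.84%). Of 21 cells with Penk and none of the other 4 subtype genes at that level, 21 had Htr3a at 100 CPM or more. Of the 349 cells with Penk under 100 CPM, 128 had it (36.7%). Median levels of Htr3a were 1307 and 17.3 CPM, with medians of 5174 and 4865 genes. A Penk read at any level was seen in 82 of the 371 cells (22.1%), so some of the 349 had Penk reads. Summed per experiment, Htr3a had 1930.2 ± 653 against 332 ± 96.1 CPM (log2 change 2.68, SE 0.28, edgeR adjusted p = 1.3e-04, higher in 6 of 6 experiments). It passed in 13 of 13 alternatives (2.37 to 3.42; adjusted p 3.2e-06 to 0.0284). Neurons with Spon1 (chromosome 7, 113765998 to 114043370), 43 of the 371 (11.6%, 8.52% to 15.3%), had more of the neuropeptide gene Tac1 (chromosome 6, 7554879 to 7565834). Of 37 cells with Spon1 alone of these genes at 100 CPM or more, 30 had Tac1 at that level (81.1%). Of the 328 cells with Spon1 under 100 CPM, 150 had it (45.7%). Median levels of Tac1 were 1535 and 67.9 CPM, with medians of 5153 and 4888 genes. A Spon1 read at any level was seen in 147 of the 371 cells (39.6%), so some of the 328 had Spon1 reads. Tac1 had 1721 ± 751 against 256 ± 131 CPM (log2 change 2.92, SE 0.33, adjusted p = 2.2e-05, higher in 7 of 7) and passed in 14 of 14 alternatives (2.47 to 3.20; adjusted p 1.0e-07 to 0.0276). P2rx3 in neurons with Cdh13 had a log2 change of 1.22 (adjusted p = 0.0130) that did not pass in 7 of 14 alternatives (0.0021 to 0.747). The 22 Penk cells lay in clusters 1, 2, 4 and 5 (10, 1, 7 and 4). Of the 43 Spon1 cells 1 was in cluster 6 and 0 in cluster 7. The comparison cells included clusters 6 and 7, and no test was made within clusters. The pairs cannot be told apart from differences between clusters.

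The numbers of other genes called in these cells did not hold. The 426 genes of Penk cells were 4, 15, 11, 17, 12 and 13 without JC07, JC08, JC09, JC10, JC11 and JC12. The 219 of Spon1 cells were 20, 17, 12, 38, 26, 418 and 38 without JC04, JC05, JC07, JC08, JC09, JC10 and JC11, and the 9 of Cdh13 cells were 4, 3 and 1 without JC04, JC05 and JC09.

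Egr2 at 100 CPM or more was seen in 15 neurons (4.04%), Cdh4 in 10 (2.70%) and Cdh13 in 38 (10.2%); Egr2 and Cdh4 cells were not tested, because too few experiments had at least 2 of them without another subtype gene. Of the 371 neurons 118 (31.8%) had at least 1 of the 5 subtype genes, 109 had exactly 1 and 9 had 2 or more. Shuffling each gene over the cells of an experiment gave a median of 14 with 2 or more (95% of shuffles 9 to 20). As few as 9 came in 322 of 10000 shuffles, so the overlap was near the edge of what shuffling gives. The 5 genes were chosen on these cells as subtype genes, which favours a low overlap beforehand, so nothing follows about chance. The level of 100 CPM matters for these counts, because 11 Penk, 11 Egr2, 8 Cdh4, 35 Cdh13 and 29 Spon1 cells lay between 50 and 200 CPM.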
